A study of Mus musculus with 32 samples.

How the data were processed

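The series holds 1 table of raw counts per gene, deposited by the authors, for 32 libraries made from mouse cerebral cortex at 6 weeks of age. Per the labels' protocols, total RNA was depleted of ribosomal RNA before library preparation. Per the submitters' processing notes, reads were handled with bcl2fastq 2.20, STAR 2.7.9a and featureCounts of Subread 1.6.4, with the builds GRCm38.p6 and GRCh38; the role of each build, the strand setting of the counting and the annotation release are not stated. The counts deposited by the authors are whole numbers with no normalization. Without a stated strand setting, reads of a gene and of a gene that overlaps it on the other strand cannot be told apart, and counts of near-identical copies, such as those of pseudogenes, are uncertain.

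The table has 55401 genes with Ensembl identifiers and symbols. Coordinates were taken by identifier from the mouse annotation of GRCm38 for 55141 of them; the 260 without coordinates hold 0.00633% of the counts. Each library was assigned to its genotype and sex by its label, and replicate numbers follow the order of the labels within a genotype. All 32 columns of counts were used. Library totals ran from 5795479 to 11189548 counts, with a median of 7883104.5. Intervals of count ratios are 95% exact binomial intervals and cover counting error only, because reads amplified by PCR without molecular identifiers are not independent molecules.

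The choices in this paragraph and the next were made before the data were examined. Counts were analysed with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr with the genotype as group, which left 16042 genes holding 99.7% of the counts, and libraries were scaled by TMM factors. A quasi-likelihood model with terms for genotype and sex was fitted to all 32 libraries, so that the 3 genotypes share 1 estimate of the spread. The 3 pairwise contrasts were tested with the quasi-likelihood F test, and p was adjusted over all tested genes by the Benjamini-Hochberg method with a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of F. A second model with the interaction of genotype and sex tested whether a change differed by sex. CPM, counts scaled to a common library size, are normalised by the same factors, and log2 CPM uses a prior count of 2. Because copy number alone changes genes inside the engineered regions, counts of changed genes are given outside 3 segments: chromosome 16 from Mrpl39 to Zbtb21 (84717576 to 97962622), chromosome 16 from Lipi to Ncam2 (75540514 to 81626828) and chromosome 17 from its start to the end of Pde10a at 8986648. The first is the region that both aneuploid genotypes carry in an additional copy, and the other 2 are parts that only 1 of the aneuploid chromosomes would add without its deficiency. Their bounds come from background knowledge, since the labels give none. The 3 segments leave 15909 tested genes outside.

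The fold of a segment in an animal is the median over its tested genes of log2 CPM minus the mean of +/+ animals of the same sex. Group means of it were compared by permutation tests with 100000 permutations, counting both directions. Lists of 33 gene groups were fixed: markers of the cell types of cortex, markers of regions and tissues that a dissection can include, synaptic and adhesion gene families, stress and interferon responses, and core cellular machinery. Genes inside the segments were left out of every list except that of the chromosome 16 segment. Of the listed symbols, Ctgf was found as Ccn2 and Tac3 as Tac2, and Ahsp and Pcdha10 were not found. Lists with at least 5 tested members were compared with all other genes by camera of limma 3.58.1 with a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with a correlation estimated from the data and fry are alternatives; fry asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes. Named genes follow a rule: outside the segments, and without pseudogenes and genes with provisional symbols such as Gm or Rik numbers, the 8 highest and 8 lowest fold changes among genes past the threshold with a mean log2 CPM of 0 or more, and the 4 further genes with the smallest adjusted p. The rule adds 20 fixed genes of the chromosome 16 segment, the genes at the segments' ends, up to 4 members with the smallest adjusted p of each list that passes or has a changed member, and up to 5 genes of the interaction. Other genes that are named were chosen after their values were seen, which is said at each. The change shared by the aneuploid genotypes was measured as the covariance and Pearson correlation of their log2 fold changes over genes outside the segments. It was set beside 100 draws of unchanged groups of the same sizes against shared controls, and repeated with the +/+ animals split into 2 sets of 6 in 100 ways. Shared genes and shared signs were set beside the same kind of draws, each with as many genes per direction as had been called, ranked by limma's moderated t; this was added after seeing the data.

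The steps were tested on simulated counts drawn from the means and library sizes of these samples, with about 200 genes changed. Each gene was drawn independently, so variation that genes share between real libraries, such as that of the striatal markers, is missing. The recovery and false calls below hold for such independent genes and can be worse in the real data. At a true fold of 1.2, 1.5 and 2, the test of Ts65Dn;Df(17)2 against +/+ recovered 26.9%, 74.6% and 81.8% of the changed genes with 5 false calls among 16029 genes; that of Dp(16)1/Df(16)8 against +/+ recovered 28.8%, 73.1% and 90.9% with 7 false calls, also among 16029. The test of the aneuploid genotypes against each other recovered 26.9%, 74.6% and 97% with 3 false calls among 16031 genes. The interaction test in Ts65Dn;Df(17)2 recovered 1.49%, 20.9% and 59.1% among 16028 genes, and that in Dp(16)1/Df(16)8 5.97%, 33.3% and 63.6% among 16027. A list of 26 genes raised by a fold of 1.2 in Ts65Dn;Df(17)2, among 16035 genes, passed with an adjusted p of 6.06e-07 by camera with the preset correlation and 3.28e-05 with the estimated one, with 0 of the other lists called. A covariance of 0.0225 put into 5000 simulated genes beyond the shared controls was recovered as 0.0223.

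The alternatives were the DESeq2 1.42.0 Wald test, limma voom with sample quality weights, DESeq2 size factors, TMM factors without the segment genes, no filter on low counts, a filter of 1 CPM in 10 libraries, no sex term, 2 surrogate variables from sva 3.50.0, the rank of the animal number as a term, only the 2 genotypes compared, leaving out the animals numbered below 30000, each sex alone, a test against a fold of 1.2, and leaving out each library in turn. Chosen after seeing the data were a score of striatal neuron markers (the mean log2 CPM of the list) as a term, the level of the pseudogene Gm28437, split at 2.5 CPM, as a term or as a selection of +/+ libraries, both terms together, leaving out the 5 libraries with the choroid plexus transcript Ttr above 100 CPM, changing the sex of the library whose transcripts go against its label, 9 blocks of neighbouring animal numbers (a new block where the number rises by more than 5) as terms, every set of 4 or 5 +/+ libraries with the level of Gm28437 of the genotype compared, and leaving out the library in which a list score or a named gene stood apart. For each contrast, 100 splits of the same libraries into groups of the same sizes, the real one included, were fitted. Added after seeing the data were splits that exchange libraries only within blocks of animal numbers, 100 of 210 and of 2880 against +/+ and all 10 between the aneuploid genotypes, fitted without and with the blocks as terms. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.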

Results

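RNA of the cerebral cortex was sequenced from 32 mice aged 6 weeks. There were 12 euploid (+/+) animals, 6 of each sex, and 10 animals, 5 of each sex by label, of each of 2 aneuploid genotypes. Ts65Dn mice carry an additional, freestanding chromosome that joins the distal part of chromosome 16, much of which is orthologous to human chromosome 21, to the centromeric end of chromosome 17. Dp(16)1 mice carry the chromosome 16 region as a duplication within the chromosome. As background knowledge, the deficiencies Df(17)2 and Df(16)8 bring the parts that the 2 lines do not share back to the normal dose, so Ts65Dn;Df(17)2 and Dp(16)1/Df(16)8 have nearly the same additional genes in a different chromosomal form. The question of the series is which effects follow from the dose of those genes and which from the presence of an additional chromosome. Libraries held 5795479 to 11189548 counts, with a median of 8213596 in Ts65Dn;Df(17)2, 7753842.5 in Dp(16)1/Df(16)8 and 7547437.5 in +/+. Mitochondrially encoded genes took 2.32% to 3.61% of the counts and the 10 most abundant genes 5.96% to 7.46%. In 31 of the 32 libraries the Xist and Y-linked transcripts matched the label. Dp(16)1/Df(16)8 replicate 2, the library labelled female, had 14 counts of Xist, 281 of Eif2s3y and 696 of Ddx3y, and was kept with its label.

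The additional copy of the chromosome 16 segment was read out as about 1.5-fold more RNA in both aneuploid genotypes. Of the 77 tested genes between Mrpl39 and Zbtb21 (GRCm38, chromosome 16, 84717576 to 97962622; 285 annotated), 62 rose in Ts65Dn;Df(17)2 and 55 in Dp(16)1/Df(16)8 against +/+, and all 77 fold changes were above 1 in each. App, the amyloid precursor protein gene (ENSMUSG00000022892.11, 84949685 to 85173766), rose 1.41-fold in Ts65Dn;Df(17)2 and 1.47-fold in Dp(16)1/Df(16)8. Sod1, the cytosolic superoxide dismutase, rose 1.54-fold and 1.601-fold, the kinase gene Dyrk1a (ENSMUSG00000022897.15, 94570010 to 94695517) 1.48-fold and 1.49-fold, and the calcineurin regulator Rcan1 1.47-fold and 1.42-fold. Of the interferon receptor genes, Ifnar1 rose by 1.49-fold and 1.58-fold, Ifnar2 by 1.61-fold and 1.55-fold, and Ifngr2 by 1.40-fold and 1.43-fold. Il10rb, named after its values were seen, was at 1.29 and 1.47 without passing. The endocytic genes Itsn1 and Synj1, the kainate receptor subunit Grik1, the ubiquitin ligase Ttc3, the chromatin genes Hmgn1 and Brwd1, the adhesion gene Dscam and the transcription factor Ets2 all rose in both, from 1.33-fold for Dscam to 1.73-fold for Hmgn1 in Ts65Dn;Df(17)2. Pcp4, a calmodulin-binding protein gene abundant in striatum as well as cortex, rose 2.08-fold and 1.86-fold. The oligodendrocyte factors Olig1 (1.19 and 1.17) and Olig2 (1.15 and 1.301) and the potassium channel Kcnj6 (1.13 and 1.22) did not pass in either genotype, and the protease Bace2 passed in Ts65Dn;Df(17)2 (1.56-fold) and not in Dp(16)1/Df(16)8 (1.37). Adjusted p of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 5.3e-11 and 3.5e-12 for App and 1.0e-13 and 7.9e-14 for Dyrk1a, with all 10 animals of each genotype above the +/+ mean.

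Per animal, the median gene of this segment stood at 1.501-fold ± 0.025 (SD, n = 10) in Ts65Dn;Df(17)2 and at 1.516-fold ± 0.025 (n = 10) in Dp(16)1/Df(16)8, against 1.01 ± 0.021 (n = 12) in +/+. Each aneuploid genotype differed from +/+ with p = 1e-05, the smallest that 100000 permutations can give. The aneuploid genotypes were not told apart from each other by this test (permutation p = 0.194). By gene, the middle 50% of folds lay between 1.43 and 1.62 in Ts65Dn;Df(17)2, with a median of 1.504, and between 1.42 and 1.62 in Dp(16)1/Df(16)8, with a median of 1.538. In a test against a fold of 1.5, adjusted over the 77 genes, Son, a splicing cofactor gene chosen here after its values were seen, was above it in both genotypes (1.67 and 1.67). Olig1 and 2 genes also chosen afterwards, Dop1b (1.34 and 1.36) and Prdm15 (1.19 and 1.16), were below it in both. In total 2 genes were above and 7 below 1.5 in Ts65Dn;Df(17)2, and 1 above and 5 below in Dp(16)1/Df(16)8. The list of 72 tested genes of this segment passed camera in both genotypes and held with an estimated correlation (adjusted p = 3.1e-20 and 2.5e-22); 61 and 54 of its members rose over all genes, and 68 and 70 adjusted over the list alone.

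**Figure D1:**
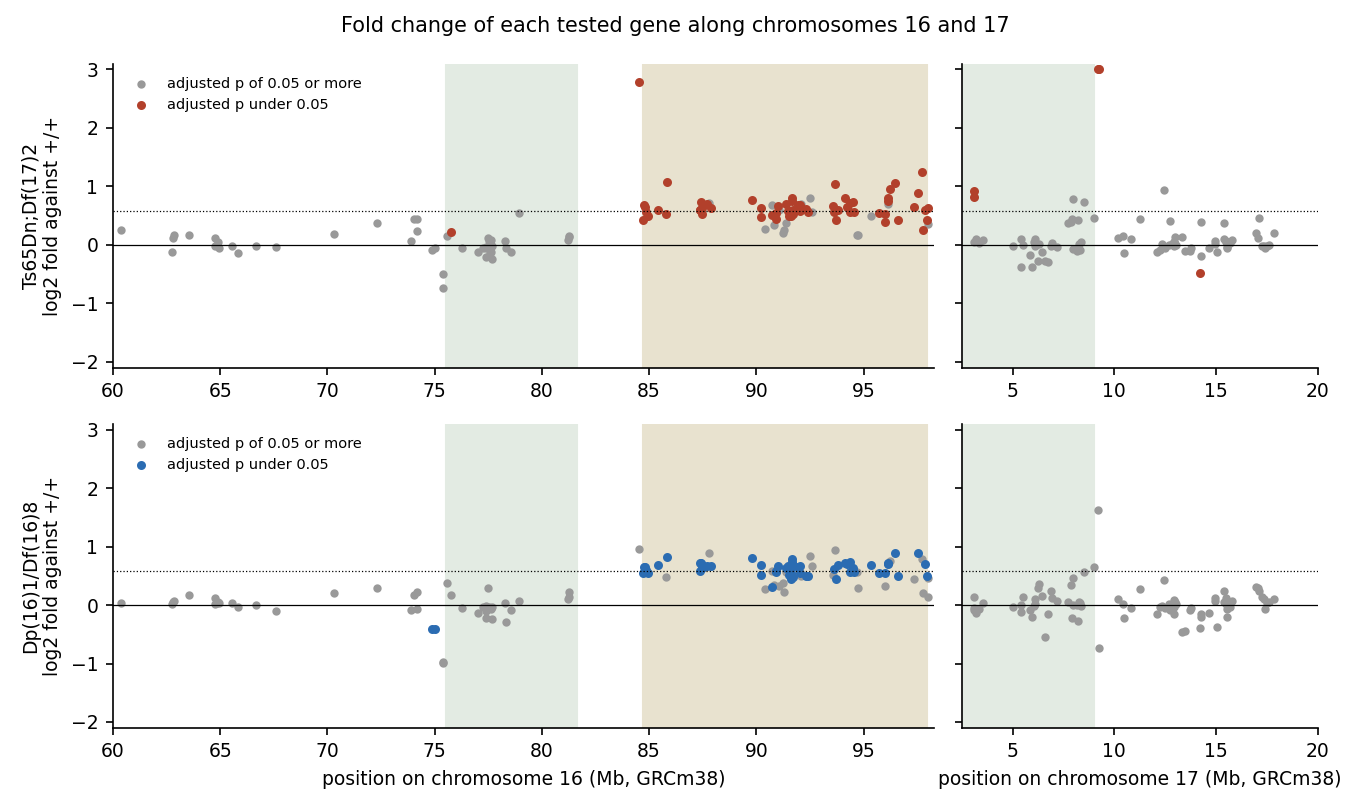
Log2 fold change against +/+ (y axis) of each tested gene by its position on the distal part of chromosome 16 and the start of chromosome 17 (x axis, Mb of GRCm38), for each aneuploid genotype; coloured points have an adjusted p under 0.05, the 3 segments are shaded, and values beyond 3 are drawn at 3. Genes of the distal chromosome 16 segment lie around the 1.5-fold line in both genotypes, with medians of 1.504 and 1.538.

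The parts of the 2 rearranged chromosomes that the deficiencies should bring back stayed near the +/+ level. The 22 tested genes from Lipi to Ncam2 on chromosome 16 (75540514 to 81626828) gave a fold per animal of 1.00 ± 0.072 (SD, n = 10) in Ts65Dn;Df(17)2 and 1.02 ± 0.12 (n = 10) in Dp(16)1/Df(16)8, against 1.01 ± 0.070 (n = 12) in +/+, with permutation p of 0.739 and 0.99. Of these genes 1 passed in Ts65Dn;Df(17)2, the chaperone gene Hspa13, named after its values were seen, at 1.16-fold; the adhesion gene Ncam2 was at 1.06 and 1.08 without passing. The 34 tested genes from the start of chromosome 17 to Pde10a gave 1.03 ± 0.039 (n = 10) and 1.02 ± 0.050 (n = 10), against 1.00 ± 0.025 (n = 12), with permutation p of 0.0521 and 0.237. With the mean over genes in place of the median the chromosome 17 fold of Ts65Dn;Df(17)2 was 1.08 (permutation p = 0.00138), without the animals numbered below 30000 it was 1.035 (p = 0.0204), and it passed without +/+ replicate 5 (p = 0.0142) and without Ts65Dn;Df(17)2 replicates 3 (p = 0.0215) and 4 (p = 0.0132). Scaf8 was at 1.03 and 0.968 and Pde10a, a phosphodiesterase abundant in striatum, at 1.65 and 1.48; neither passed. Pisd-ps2 and Gm21926, pseudogenes within the first 3114795 bases of chromosome 17 and named after their values were seen, rose 1.89-fold and 1.76-fold in Ts65Dn;Df(17)2; their counts are uncertain because near-identical copies exist elsewhere.

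**Figure D2:**
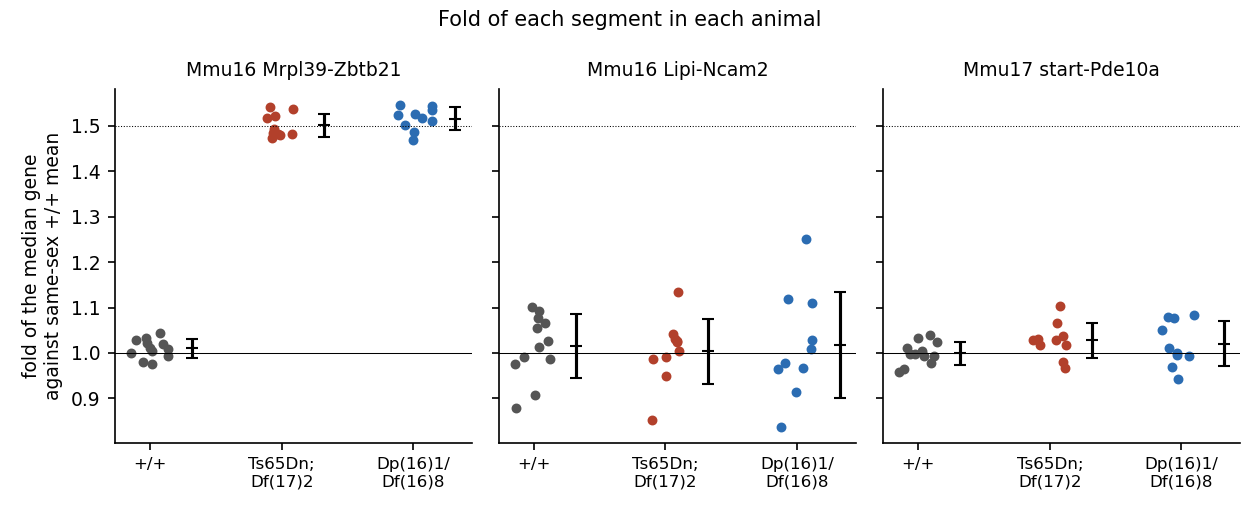
Fold of the median gene of each segment in each animal against the +/+ mean of its sex (y axis), with the group mean and SD, for the 3 genotypes; the dotted line marks 1.5. The distal chromosome 16 segment ran from 1.47 to 1.54 in Ts65Dn;Df(17)2 and from 1.47 to 1.55 in Dp(16)1/Df(16)8, with no overlap with +/+, which ran from 0.975 to 1.04.

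In Ts65Dn;Df(17)2 cortex, genes outside the segments changed in both directions, mostly by small amounts. The basement membrane collagens Col4a2 (ENSMUSG00000031503.13, chromosome 8, 11312805 to 11449287) and Col4a1 (11198423 to 11312826), which lie head to head, rose by log2 0.53 (SE 0.062) and 0.41 (SE 0.059), from 89.1 ± 9.55 to 128 ± 12 CPM and from 68.9 ± 7.35 to 91.7 ± 9.08 CPM (SD, n = 12 and n = 10). Smyd1, a muscle methyltransferase gene, rose by log2 1.43 (SE 0.23), from 1.43 ± 0.661 to 3.88 ± 1.02 CPM. Arhgef17 fell by 0.28 on the log2 scale (SE 0.039) and Exoc3, of the exocyst, rose by 0.28 (SE 0.047). Among the highest fold changes was that of Tyr, the tyrosinase of pigment cells (chromosome 7, 87424771 to 87493512), with 75 to 168 counts in each Ts65Dn;Df(17)2 library and 0 to 3 in each +/+ library. The ratio of counts, scaled by library sizes and their TMM factors, was 160 (95% interval 80.8 to 371). The long non-coding RNA C87487 (chromosome 17, 9189126 to 9223664) had 213 counts in the 10 Ts65Dn;Df(17)2 libraries and 1 in the 12 +/+ libraries, a ratio of 231 (95% interval 41 to 9170). Other high changes were those of Nts, Pi15, Dlx6os2, Npffr1 and Rsad2, from log2 0.92 to 1.40, and the lowest those of Cyp11a1, Dnah6, Cd6, Tcap, Tspan11, Alox12b, Adam33 and Wnt10a, from log2 -1.89 to -1.32. Dnah6 reached 23 CPM in replicate 1 of this genotype, where the others had 2.72 to 9.65. Each of these 20 genes moved in its direction in at least 8 of the 10 animals, and adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment ran from 3.1e-20 for Tyr to 0.0491 for Npffr1, with 4.6e-07 for Col4a2.

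The count behind these genes was 572 outside the segments (216 up, 356 down) and 637 with the segments (281 up, 356 down), of 15909 and 16042 tested. It depended on single libraries. The outside count fell to 298, 241, 231, 340, 265 and 245 without +/+ replicates 1, 4, 5, 7, 9 and 10, and to 361, 201, 333, 214, 295 and 358 without Ts65Dn;Df(17)2 replicates 1, 2, 4, 7, 8 and 9, and rose to 1041 and 1416 without +/+ replicates 6 and 11. The count with the segments moved by over 1.5 times without 13 of these 14 libraries, all but Ts65Dn;Df(17)2 replicate 1, to between 264 and 1486. Markers of striatal neurons differed between libraries at the same time: their mean log2 CPM was 6.57 ± 0.612 (SD, n = 10) in Ts65Dn;Df(17)2, 6.00 ± 1.35 (n = 10) in Dp(16)1/Df(16)8 and 5.35 ± 1.40 (n = 12) in +/+. Ts65Dn;Df(17)2 was above +/+ (permutation p = 0.0193). By the same test Dp(16)1/Df(16)8 was not told apart from +/+ (permutation p = 0.283), nor were the aneuploid genotypes from each other (permutation p = 0.239). With this score as a term, an alternative chosen after seeing the data, 64 of the 572 genes kept their call and 24 others were added; Tyr, C87487, Smyd1, Col4a1, Col4a2, Arhgef17, Exoc3 and Dnah6 were among those kept. With blocks of neighbouring animal numbers as terms, also chosen after seeing the data, 28 genes changed outside the segments, 23 of them among the 572. The 572 genes went from a median size of log2 0.35 (median SE 0.0908) to 0.23 (0.0835) with the score, so changes shrank, and to 0.32 (0.119) with the blocks, where mostly the error rose.

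**Figure D3:**
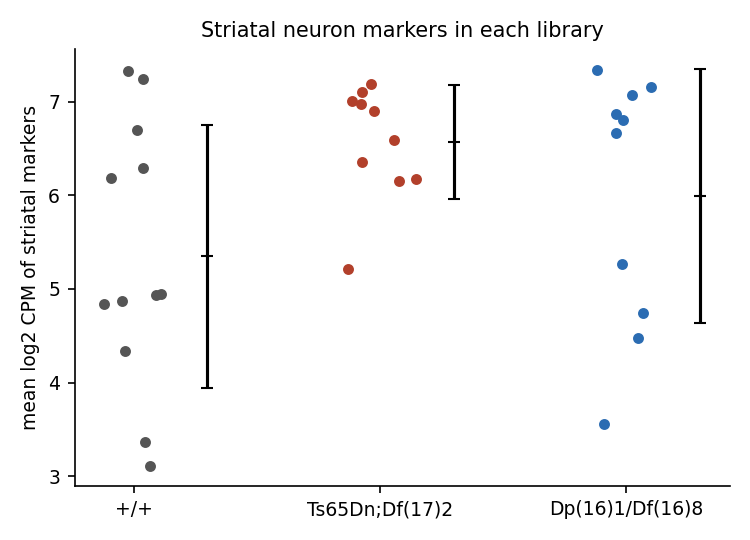
Mean log2 CPM of the 15 tested striatal neuron markers (y axis) in each library by genotype, with the group mean and SD. The +/+ libraries ran from 3.11 to 7.33, the Ts65Dn;Df(17)2 libraries from 5.21 to 7.20 and the Dp(16)1/Df(16)8 libraries from 3.56 to 7.34.

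By gene group, some excitatory cortical neuron markers were lower and some interferon-stimulated transcripts higher in Ts65Dn;Df(17)2 than in +/+, and their lists passed camera with the preset correlation and not with an estimated one. Of 20 excitatory neuron markers 6 fell, 0 rose and 14 did not pass; adjusted over the list alone 12 fell and 2 rose. Rorb, a layer 4 factor, fell by 0.55 on the log2 scale, Lamp5 by 0.76, and the upper layer factors Cux2 and Cux1 by 0.50 and 0.24. The list passed with an adjusted p of 3.0e-04, and did not with an estimated correlation (adjusted p = 0.545 with an estimated correlation). Of 26 interferon-stimulated genes 3 rose and 0 fell, 5 and 0 adjusted over the list alone, with 24 of 26 fold changes above 1. Among those that rose, Rsad2, an antiviral enzyme, rose by log2 0.92 and Lgals3bp by 0.48, while Ifit1 was at 0.62 without passing. This list passed with an adjusted p of 1.5e-04 (adjusted p = 0.545 with an estimated correlation). By fry, which does not compare a list with other genes, the excitatory and interferon lists each had an adjusted p of 0.0438. With the striatal score as a term, Rorb, Lamp5, Cux2, Cux1, Rsad2 and Lgals3bp no longer passed, with adjusted p of 0.134, 0.333, 0.365, 0.169, 0.176 and 0.298 by edgeR's quasi-likelihood test.

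Lists of other cell types and of neuronal activity passed camera in the same comparison, again with the preset correlation and not with an estimated one. Of 20 interneuron markers 2 rose and 0 fell, with 6 up and 3 down adjusted over the list alone: the non-coding RNA Dlx6os1 rose by log2 0.62 and Gad1, which makes GABA, by 0.43, and the list passed with an adjusted p of 0.0322 (adjusted p = 0.481 with an estimated correlation). Gad1 and Dlx6os1 are expressed by striatal neurons as well. Of 20 astrocyte markers 3 fell, Clu by 0.22, Fgfr3 by 0.23 and Aldoc by 0.18 on the log2 scale, and 0 rose, with 7 down and 2 up adjusted over the list alone; the adjusted p was 0.0199 (adjusted p = 0.545 with an estimated correlation). All 15 tested striatal neuron markers, among them the dopamine receptor Drd1 (log2 0.77), Penk (0.86) and Tac1 (0.92), were positive and 0 passed by edgeR, as adjusted over the list alone; 15 of 15 gave the list an adjusted p of 1.4e-05 (adjusted p = 0.606 with an estimated correlation). Of 23 immediate early genes of neuronal activity 0 passed, all 23 were negative, with Nptx2 at log2 -0.63 and Egr3 at -0.57, and the list had an adjusted p of 4.8e-04 (adjusted p = 0.606 with an estimated correlation). Of 20 endothelial and mural markers 0 passed and 17 were positive, with Kdr at 0.41 and a list p of 0.00558 (adjusted p = 0.606 with an estimated correlation). Of 16 meningeal markers Col3a1 alone rose, by log2 0.87, with 2 up and 1 down adjusted over the list alone and a list p of 0.0182 (adjusted p = 0.606 with an estimated correlation).

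Among cellular functions, the lists of cholesterol synthesis, presynaptic release, stress response and mitochondrially encoded genes passed camera in Ts65Dn;Df(17)2 with the preset correlation and not with an estimated one, and few of their genes passed. Of 24 cholesterol genes 3 rose, Hmgcs1 by log2 0.22, Msmo1 by 0.18 and the sterol transporter Stard4 by 0.21, also 3 adjusted over the list alone, and 21 were positive, with a list p of 0.00355 (adjusted p = 0.545 with an estimated correlation). Of 28 genes of presynaptic release the scaffold Bsn fell, by 0.33 on the log2 scale, with 8 down adjusted over the list alone and a list p of 0.00355 (adjusted p = 0.606 with an estimated correlation). Of 25 genes of the unfolded protein and integrated stress response 0 passed and 6 were positive, with Calr at log2 -0.14 and Sdf2l1 at -0.60, and a list p of 0.0199 (adjusted p = 0.606 with an estimated correlation). Of 10 mitochondrially encoded genes 0 passed and 1 rose adjusted over the list alone, with mt-Nd4 at log2 0.20 and a list p of 0.0464 (adjusted p = 0.606 with an estimated correlation). For the lists just named with 0 genes past the threshold, the unadjusted threshold of 0.05 was passed by 3491 genes of the whole comparison, and DESeq2 and limma voom called 1069 and 1357 genes in all where edgeR called 637.

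The other lists did not pass camera in Ts65Dn;Df(17)2, although some members changed. Among 41 human chromosome 21 orthologues on chromosomes 10 and 17, which neither rearrangement adds, the cystathionine synthase Cbs fell by 0.44 and the centrosomal Pcnt by 0.23 on the log2 scale, with 2 up and 3 down adjusted over the list alone and a list p of 0.76. The glutamate receptor genes Gria1 and Grik2 rose by log2 0.34 and 0.37 while the postsynaptic scaffold Shank1 fell by 0.41, with a list p of 0.119, and 2 up and 5 down adjusted over the list alone. The GABA receptor subunit Gabrg1 rose by 0.62 (list p 0.76; 1 up and 2 down adjusted over the list alone). The guidance gene Sema6d rose by 0.32 while Epha4 and Efna5 fell by 0.35 and 0.61 (list p 0.349), with 7 up and 3 down adjusted over the list alone. Col25a1 rose by 0.60 with the collagens Col4a1 and Col4a2 in the matrix list (list p 0.12), with 5 up and 1 down adjusted over the list alone. Single genes changed in 5 further lists: the microglial protease Ctss rose by log2 0.44 (list p 0.304), Lhfpl3 of oligodendrocyte precursors rose by 0.53 (0.352), Rora of the thalamic and septal list fell by 0.37 (0.851), the p53 target Ccng1 fell by 0.43 (0.184) and Cox8a of oxidative phosphorylation fell by 0.15 (0.549). Adjusted over the list alone, these 5 lists had 1, 2, 1, 0 and 0 genes up and 0, 0, 2, 1 and 0 down. No member passed by edgeR, adjusted over all genes, in the lists of oligodendrocytes and myelin (list p 0.368), choroid plexus and ependyma (0.549), blood (0.801), hippocampus (0.816), ribosomal proteins (0.38), chaperones (0.816), proteasome (0.389), cell cycle (0.352), clustered protocadherins (0.509) and sex-linked controls (0.847). Adjusted over the list alone, 1 hippocampal marker fell and no other member of these lists passed.

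In Dp(16)1/Df(16)8 cortex fewer genes outside the segments passed, and several were ones that had changed in Ts65Dn;Df(17)2. Col4a2 and Col4a1 rose by log2 0.50 (SE 0.062) and 0.41 (SE 0.060), to 125 ± 13.1 and 91.5 ± 8.54 CPM (SD, n = 10), and Smyd1 by 1.19 (SE 0.23), to 3.31 ± 1.25 CPM. The secreted Spp1 rose by log2 0.62 (SE 0.15), the kinase gene Cdkl3 by 0.43, Mbd6 by 0.28, the focal adhesion gene Pxn by 0.27 and Luzp2 by 0.26. Spink10 (0.54), the mitochondrial carrier Ucp2 (0.53), Cbs (0.48), Phospho1 (0.39), the helicase Dhx37 (0.38), Rfx5 (0.37), Pdlim7 (0.32), D10Wsu102e (0.31), Ptges2 (0.31), Tpcn1 (0.23) and Arhgef17 (0.19) fell by these amounts on the log2 scale. Tyr, with 2 to 7 counts per library, was 5.76-fold (95% interval 2.65 to 14.3) above +/+. Each of these 20 genes moved in its direction in at least 9 of the 10 animals, with adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment from 2.0e-06 for Col4a2 to 0.0479 for Spink10.

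Outside the segments 37 genes changed (12 up, 25 down), and 92 with the segments (67 up, 25 down). Without Dp(16)1/Df(16)8 replicate 1 the outside count was 164 and the whole count 222, without +/+ replicate 11 they were 107 and 165, and without Dp(16)1/Df(16)8 replicate 9 the outside count was 21. DESeq2 and limma voom called 85 and 98 genes outside the segments. With blocks of neighbouring animal numbers as terms, an alternative chosen after seeing the data, 107 genes changed outside the segments. This count and the 28 of Ts65Dn;Df(17)2 with blocks do not compare sizes. The blocks raised the median SE of the 37 genes from 0.0595 to 0.0655 and that of the 572 genes of Ts65Dn;Df(17)2 from 0.0908 to 0.119, with median sizes of log2 0.30 (0.28 before) and 0.32 (0.35 before).

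In Dp(16)1/Df(16)8, 10 lists passed camera against +/+ with the preset correlation, and 1 of them with an estimated one, that of the distal chromosome 16 segment. Interferon-stimulated genes passed with an adjusted p of 3.7e-06 (adjusted p = 0.661 with an estimated correlation): 24 of 26 were positive, with Ifit1 at log2 0.67, 0 passed, and 3 rose adjusted over the list alone. Their score was 3.34 in replicate 4, where the other 9 libraries had 2.24 to 2.65. Without that library, an alternative chosen after seeing the data, the group mean went from 2.474 to 2.378, against 2.206 in +/+. The list p was then 0.0016 (adjusted p = 0.697 with an estimated correlation) and Ifit1 was at log2 0.50. Endothelial and mural markers passed with 3.2e-05 (adjusted p = 0.661 with an estimated correlation), with 18 of 20 positive, Kdr at log2 0.55, 0 past the threshold and 6 up adjusted over the list alone. Excitatory neuron markers had 4 of 20 positive, 0 past the threshold and 0 adjusted over the list alone, Rorb at log2 -0.32 and a list p of 0.00579 (adjusted p = 0.661 with an estimated correlation). Of the astrocyte markers Clu fell by 0.18 on the log2 scale, with 3 down and 1 up adjusted over the list alone, and the list p was 0.0354 (adjusted p = 0.661 with an estimated correlation). Striatal markers were all positive with 0 past the threshold, also over the list alone, and a list p of 0.00579 (adjusted p = 0.74 with an estimated correlation). All 23 immediate early genes were negative, Egr3 at log2 -0.38, with 0 past the threshold in either way and a list p of 1.9e-04 (adjusted p = 0.661 with an estimated correlation). Mitochondrially encoded genes had 9 of 10 positive, mt-Nd4 at 0.15, and a list p of 0.00307 (adjusted p = 0.661 with an estimated correlation). Presynaptic genes had 6 of 28 positive, Bsn at log2 -0.22, and a list p of 0.00601 (adjusted p = 0.661 with an estimated correlation). The clustered protocadherins, cell adhesion genes of neurons, had 17 of 55 positive, Pcdhga2 at log2 -0.44, and a list p of 0.04 (adjusted p = 0.661 with an estimated correlation). In these last 3 lists 0 members passed, also adjusted over the list alone. Beside the counts of 0, 2050 genes of the comparison had an unadjusted p under 0.05, and DESeq2 and limma voom called 145 and 158 genes in all where edgeR called 92. The other 23 lists did not pass; among them Cbs fell in the list of human chromosome 21 orthologues (p 0.83; 2 down adjusted over the list alone), and Col4a1 and Col4a2 rose in the matrix list (p 0.364; 3 up adjusted over the list alone).

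Set directly against each other, the aneuploid genotypes differed in few genes. Outside the segments 6 of 15909 genes differed, 5 higher and 1 lower in Ts65Dn;Df(17)2. Tyr had 1178 counts in the 10 Ts65Dn;Df(17)2 libraries and 38 in the 10 Dp(16)1/Df(16)8 libraries, a ratio of 27.8 (95% interval 20.1 to 39.4), and C87487 had 213 and 5, a ratio of 38.1 (16.1 to 119). The other 4 were named after their values were seen. Gm49806 (chromosome 17, 9246550 to 9248548), 259902 bases past the end of Pde10a as C87487 is 202478 bases past it, had 287 and 2 counts. A730009L09Rik (chromosome 16, 84515121 to 84523888), 193688 bases before the distal segment, had 204 and 51 counts, a ratio of 3.58 (2.62 to 4.97). B230307C23Rik (chromosome 16, 97997315 to 98031801), 34693 bases past Zbtb21, had 1003 and 646, a ratio of 1.39 (1.26 to 1.54). Its fitted fold against +/+ was 1.54 in Ts65Dn;Df(17)2, the value of 1 additional copy, and 1.10 in Dp(16)1/Df(16)8. Because the bounds of the segments come from background knowledge, genes close to their ends need not lie outside the additional material. Gm28437, a pseudogene on chromosome 1 whose counts are uncertain, was lower in Ts65Dn;Df(17)2, at 0.661 ± 0.218 against 5.11 ± 0.828 CPM (SD, n = 10 and n = 10). Inside the segments Pisd-ps2 and Gm21926 were higher, which makes 8 genes in all by edgeR, where DESeq2 and limma voom called 8 and 7. Of the 77 genes of the distal chromosome 16 segment 0 differed by edgeR. In the whole comparison 658 genes had an unadjusted p under 0.05, and 646 of them lay outside the segments. With the level of Gm28437 as a term 0 genes differed, since that level separates the 2 genotypes themselves. With blocks of neighbouring animal numbers as terms 2 of the 6 genes outside the segments kept their call. The 6 genes then went from a median size of log2 3.84 (median SE 0.291) to 3.22 (0.478).

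**Figure D4:**
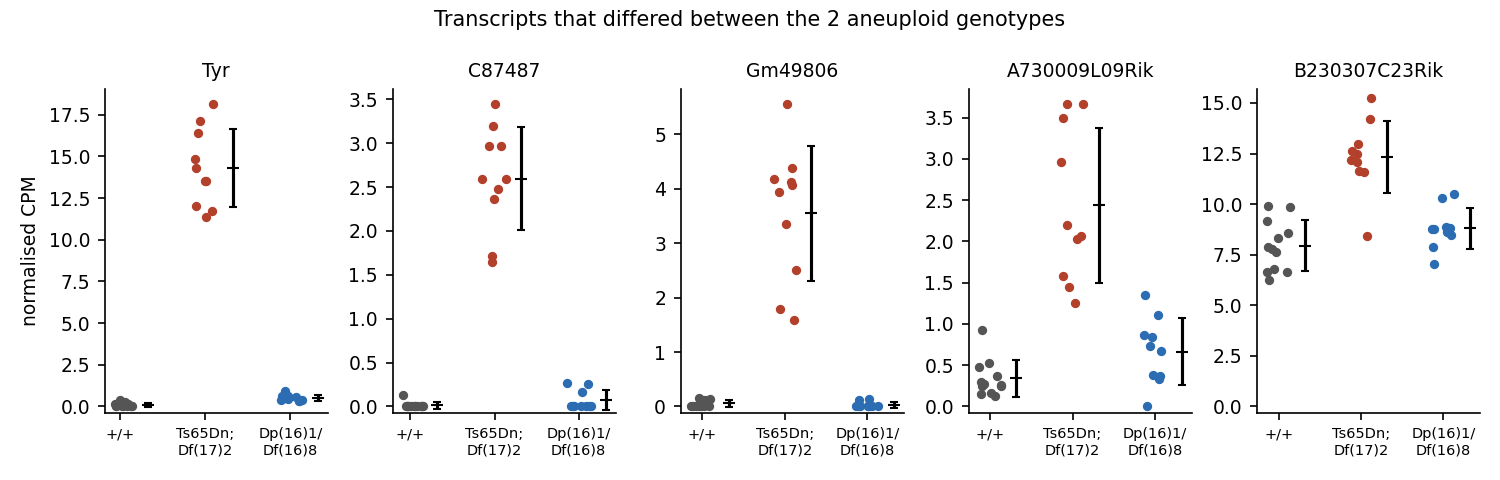
Normalised CPM (y axis) in each library, by genotype, of transcripts that differed between the aneuploid genotypes, with the group mean and SD. Tyr had 75 to 168 counts per library in Ts65Dn;Df(17)2 and 2 to 7 in Dp(16)1/Df(16)8, and C87487 13 to 29 and 0 to 2.

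Between the aneuploid genotypes 2 lists, the clustered protocadherins and the striatal markers, passed camera with the preset correlation and neither did with an estimated one. The protocadherins were higher in Ts65Dn;Df(17)2, with 46 of 55 positive, Pcdhga2 at log2 0.51 and Pcdhga3 at 0.38, 0 genes past the threshold and 2 up adjusted over the list alone, and an adjusted p of 9.3e-05 (adjusted p = 0.862 with an estimated correlation). Their score stood apart in Ts65Dn;Df(17)2 replicate 5, at 3.97 where the other 9 had 3.58 to 3.76. Without that library, an alternative chosen after seeing the data, the group mean went from 3.715 to 3.687, against 3.624 in Dp(16)1/Df(16)8. The list p was then 0.0182 (adjusted p = 0.763 with an estimated correlation). The striatal markers were all positive, with Drd1 at log2 0.25, 0 past the threshold in either way and a list p of 0.00499 (adjusted p = 0.862 with an estimated correlation). The list of the distal chromosome 16 segment had 32 of 72 genes positive and a p of 0.691. The median, mean and test of a list differed in sign only among lists that did not pass: hippocampus in Ts65Dn;Df(17)2; hippocampus, oligodendrocytes, their precursors and the chromosome 21 orthologues in Dp(16)1/Df(16)8; and between the aneuploid genotypes the distal segment, microglia, thalamus, ribosomal proteins, mitochondrially encoded genes and cell cycle. Across the 3 comparisons the list of that segment was the only one to hold with an estimated correlation, in the 2 comparisons with +/+.

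The changes of the aneuploid genotypes against +/+ resembled each other, in part because the same +/+ libraries enter both comparisons. Among the 216 and 12 genes that rose outside the segments 9 were shared, where independent lists would share 0.163, and among the 356 and 25 that fell 18 were shared, against 0.559. These 2 values leave out the shared +/+ libraries. Ranked by limma's moderated t, equal numbers of genes shared 8 and 13, where unchanged groups set against the same +/+ libraries shared a mean of 2.69 (0 to 7 over 100 draws) and 6.56 (0 to 15). With the +/+ animals split into 2 separate sets of 6, the means were 3.77 and 4.09, against 0.31 and 0.55 for unchanged groups. Col4a1, Col4a2, Smyd1, Spp1, Cdkl3, Pxn, Mbd6, Luzp2 and Tyr rose in both, and Arhgef17, Cbs, Clu, Dhx37, D10Wsu102e and Rfx5 were among those that fell in both. Of the 572 genes changed in Ts65Dn;Df(17)2, 565 had the same sign in Dp(16)1/Df(16)8, with a median size of log2 0.35 in the former and 0.22 in the latter, and all 37 genes changed in Dp(16)1/Df(16)8 had the same sign in Ts65Dn;Df(17)2. Ranked by limma's moderated t, 566 of 572 and 37 of 37 had the same sign. Unchanged groups gave a mean of 487 (319 to 569) and 32.8 (19 to 37), so with shared +/+ libraries these shares lie within the range of groups with no change. With the +/+ animals split, the means were 504 of 572 and 31.3 of 37, against 292 and 19.3 for unchanged groups (124 to 517 and 6 to 34). Across 15909 genes, which are not independent replicates, the fold changes had a Pearson correlation of 0.734 and a covariance of 0.0364. Unchanged groups set against the same +/+ libraries gave a mean correlation of 0.471 and a mean covariance of 0.0112, with 1 of 100 draws as high as observed, and a covariance difference of 0.0252. With the +/+ animals split into 2 separate sets of 6, the mean correlation was 0.429 (0.157 to 0.552 over 100 splits) and the mean covariance 0.0252 (0.00941 to 0.0315). Unchanged groups gave a mean correlation of -0.00699 (-0.618 to 0.513) and a mean covariance of -3.5e-04 (-0.0336 to 0.0233). Of 100 such draws 2 were as high as the mean observed correlation and 0 as the mean observed covariance. The observed values are means over splits of the same animals, while each draw is a single value. With the striatal score removed, the correlation was 0.58 against 0.503, and 23 of 100 draws were as high. The covariance difference was 0.00662, with 6 of 100 draws as high in covariance.

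**Figure D5:**
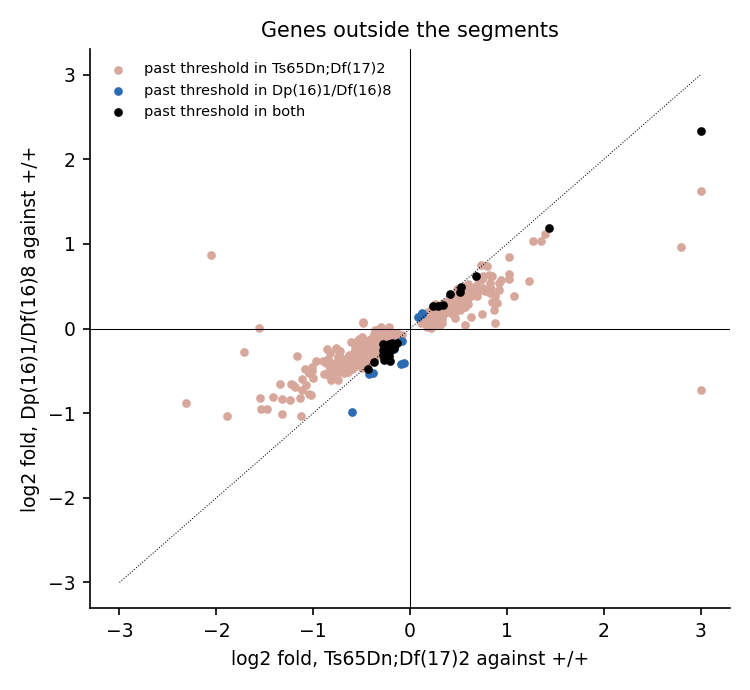
Log2 fold change against +/+ of genes outside the segments in Ts65Dn;Df(17)2 (x axis) and Dp(16)1/Df(16)8 (y axis), coloured by the comparison in which the gene passed; values beyond 3 are drawn at 3, and the dotted line marks equal changes. Of the 572 genes that passed in Ts65Dn;Df(17)2, 565 lie on the same side of 0 in both.

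Changes that depended on sex were not detected. Dp(16)1/Df(16)8 replicate 2, labelled female but with Y-linked transcripts, was counted as female in these tests. The interaction of genotype and sex had 0 genes past the threshold in Ts65Dn;Df(17)2, in Dp(16)1/Df(16)8 and between them by edgeR's quasi-likelihood test, with 787, 804 and 491 genes at an unadjusted p under 0.05; DESeq2 called 0, 2 and 0 and limma voom 0, 0 and 0. Without Dp(16)1/Df(16)8 replicate 6 edgeR called 2 genes in Dp(16)1/Df(16)8 and 2 between the aneuploid genotypes. In simulated data the interaction test recovered 20.9% of genes whose change differed by a fold of 1.5 between the sexes in Ts65Dn;Df(17)2 and 33.3% in Dp(16)1/Df(16)8.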

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

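Chosen only after their results were seen were, for the gene counts, the tests with the striatal score as a term, with the level of Gm28437 and with blocks of animal numbers, the splits within these blocks and the comparison of splits with the striatal score, and, for the sex label, the search for a second library against its label and the counts of Tyr. In groups of 10 libraries, a value was examined when its gap to the nearest other library, divided by the range of its group, was above Dixon's 95% critical value. This met 27 of 300 groups, where chance meets about 1 in 20, or 15. Many of them lay in the same libraries, so they are not independent.

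Neuronal transcripts of Dp(16)1/Df(16)8 replicate 1 stood apart from those of the other 9 libraries of its genotype. It had 171 CPM of the cortical neuron gene Lamp5 (others 38 to 76.1), 278 of the activity gene Egr3 (96.8 to 181), 76.6 of Efna5 (23 to 39.1) and 342 of Epha4 (210 to 275). It was low in the glutamate receptor gene Gria1, at 365 CPM (524 to 603), in Col25a1 at 56 (93.9 to 137) and in Rfx5 at 12.1 (16.8 to 21.7). It was high in Tspan11 at 11 CPM (0.803 to 4.93), Wnt10a at 6.1 (0.985 to 3), Adam33 at 4.51 (0.335 to 2.2), D10Wsu102e at 510 (371 to 440) and Scaf8 at 107 (83.3 to 94). Its score of meningeal markers was 2.29 (3 to 3.69).

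Interferon-stimulated transcripts were high in Dp(16)1/Df(16)8 replicate 4, with a score of 3.34 (others 2.24 to 2.65), 5.53 CPM of Ifit1 (1.45 to 2.81) and 22.3 of Lgals3bp (9.39 to 14.6). Ts65Dn;Df(17)2 replicate 4 had the lowest striatal score of its genotype, 5.21 (6.16 to 7.2), and was high in Bace2 at 12.1 CPM (5.48 to 8.08), Ncam2 at 319 (205 to 261) and Ttc3 at 2100 (1780 to 1950). Dnah6, which fell in Ts65Dn;Df(17)2, reached 23 CPM in replicate 1 of that genotype (2.72 to 9.65). Other values that stood apart in Ts65Dn;Df(17)2 were Cbs in replicate 6 at 17.5 CPM (9.21 to 13.5), Pcnt in replicate 9 at 56.4 (46 to 51.6), Scaf8 in replicate 7 at 107 (93.8 to 98.2) and the score of clustered protocadherins in replicate 5 at 3.97 (3.58 to 3.76). In Dp(16)1/Df(16)8 they were Tyr in replicate 3 at 0.938 CPM (0.335 to 0.626) and the cell cycle score in replicate 6 at 2.25 (1.67 to 1.98). Replicates 4 and 5 of Ts65Dn;Df(17)2 are the 2 animals numbered below 30000. No explanation was tested for these values.

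More genes changed outside the segments in Ts65Dn;Df(17)2 (572) than in Dp(16)1/Df(16)8 (37), and striatal tissue in the dissected cortex may account for a part of this. Other splits of the Ts65Dn;Df(17)2 and +/+ libraries with striatal differences of 1.22 to 1.51, where the real one was 1.22, gave 0 genes. Of the 572 genes, 85.5% changed in the direction of their slope on the striatal score within Dp(16)1/Df(16)8 libraries, against 64.7% of other genes. The higher share does not set the 572 genes apart, because genes past the threshold have larger changes, whose signs are surer. The Pearson correlation of slope and change was 0.592 for the 572 genes and 0.571 for the others. With matching libraries 21 genes changed, as few as in 6 of 50 random draws of equal size, which decides nothing. With the score as a term 88 genes changed against 37, so the score did not take away the whole excess. A mean of 15 markers may not hold all of the tissue's effect, so tissue as the whole cause is not decided. The 572 genes went from a median size of log2 0.35 (median SE 0.0908) to 0.23 (0.0835), so calls ended because changes shrank. With the score and the Gm28437 level as terms, 19 of the 572 genes kept their call and 6 were added. In Dp(16)1/Df(16)8, 14 of the 37 kept theirs and 13 were added. These counts do not show that the excess was accounted for, because Gm28437 was low in every Ts65Dn;Df(17)2 library and high in every Dp(16)1/Df(16)8 library. With both terms the 572 genes had a median size of log2 0.25 and a median SE of 0.101. The 37 genes had a median size of log2 0.26 (0.28 before) and a median SE of 0.0676 (0.0595 before). Against all sets of 4 +/+ libraries with the same level of Gm28437, a median of 23 genes changed in Ts65Dn;Df(17)2 (17 to 35 over 5 sets) and 13 in Dp(16)1/Df(16)8 (8 to 830 over 35 sets). These ranges overlap, so the sets decide nothing. An origin marked by Gm28437 cannot be told apart from genotype, because its level is low throughout Ts65Dn;Df(17)2 (3 to 8 counts) and high throughout Dp(16)1/Df(16)8 (25 to 50). With blocks of neighbouring animal numbers the counts were 28 and 107. The 572 genes kept a median size of log2 0.32 while their median SE rose to 0.119, so their calls ended because the error rose. Counts against +/+ do not test a difference between the aneuploid genotypes. Set directly against each other, these differed in 6 of 15909 genes outside the segments, by a test that recovered 26.9% of simulated 1.2-fold changes. A biological effect of the freestanding chromosome stays open.

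Dp(16)1/Df(16)8 replicate 2, the library labelled female, had Y-linked transcripts. A swap with another library of the series would leave a second library against its label, and 0 others were, which argues against it. A +/+ library is argued against by its fold of 1.51 for the distal chromosome 16 segment, where +/+ ran from 0.975 to 1.04, and a Ts65Dn;Df(17)2 library by its 4 counts of Tyr, where that genotype had 75 to 168. A wrong sex label, or a swap with an animal of the same genotype outside the series, stays open, and no biological explanation was tested.

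Chance as a source of the counts of changed genes was tested with 100 splits of the same libraries for each comparison, the real split included. With free exchange of libraries, for Ts65Dn;Df(17)2 against +/+ 1 split, the real one, reached 637 genes, or 572 outside the segments. The highest other split gave 1 gene in both. For the aneuploid genotypes against each other 1 split, the real one, reached 8 genes, or 6 outside, and the highest other gave 1 in both. For these 2 comparisons chance is excluded only if libraries can be freely exchanged, which their uneven spread over animal numbers, described below, puts in doubt. For Dp(16)1/Df(16)8 against +/+ 3 of 100 splits reached 92 genes and 4 reached 37 outside, shares under 0.05. Chance is not firmly excluded for these counts, because some other splits gave more genes than the real one. The count of 92 also holds 55 genes of the distal chromosome 16 segment, which has an additional copy. The highest other split gave 1373 genes, or 1365 outside, which points to a structure of the samples. In that split the striatal scores of the 2 groups differed by 1.65, the largest difference among the 99 other splits (median 0.493), and the number of genes at an unadjusted p under 0.05 followed this difference over the 99 (Spearman correlation 0.631). For Ts65Dn;Df(17)2 against +/+ this correlation was 0.278. There the real striatal difference was 1.22, and other splits with differences of 1.51, 1.23 and 1.22 each gave 0 genes. A striatal difference of this size thus need not change genes by itself.

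Free exchange ignores that genotypes are unevenly spread over animal numbers. With exchange only within blocks of neighbouring animal numbers, 2 of 100 splits reached 572 genes outside the segments for Ts65Dn;Df(17)2 against +/+ (highest other 1065), and with the blocks as terms 1 of 100 reached 28 (highest other 1). For Dp(16)1/Df(16)8 against +/+ 1 of 100 reached 37 (highest other 5) and, with the blocks as terms, 4 of 100 reached 107 (highest other 1092). These shares are under 0.05, but where another split gave more genes than the real one, chance is not firmly excluded. Such splits still hold libraries that differ in striatal score, so the shares concern chance and not tissue. Between the aneuploid genotypes only 10 such splits exist, too few for a share under 0.05: 1 reached 6 genes (highest other 4) and, with the blocks as terms, 1 reached 2 (highest other 0).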

How the results depend on the processing

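The terms for the striatal score and Gm28437, the selections by Gm28437 or Ttr, the changed sex label, the blocks of animal numbers and leaving out a library that stands apart were chosen after seeing the data. Where no cause is named, the cause was not tested. The labels carry animal numbers and no replicate numbers, so no pairing by replicate was made.

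Counts are given for all genes and then outside the segments. For Ts65Dn;Df(17)2 against +/+ (637 and 572), DESeq2 gave 1069 and 999, limma voom 1357 and 1284, no filter 331 and 269, 2 surrogate variables 148 and 86, and the animal rank 400 and 337. Leaving out the animals numbered below 30000, which are 2 Ts65Dn;Df(17)2 females, gave 280 and 220. Fewer libraries gave 54 and 11 in females and 60 and 14 in males, and a test against a fold of 1.2 gave 60 and 13. The striatal score gave 152 and 88, the Gm28437 level 83 and 33, both 80 and 25, blocks of neighbouring animal numbers 77 and 28, leaving out high Ttr 263 and 201, and +/+ libraries with low or high Gm28437 90 and 40 or 190 and 130. Outside the segments, sets of 4 or 5 +/+ libraries with the matching Gm28437 level gave medians of 23 or 40 in Ts65Dn;Df(17)2 and 13 or 19 in Dp(16)1/Df(16)8. With the Gm28437 level or the blocks the 572 genes kept a median size of log2 0.34 or 0.32 (0.35 without), while their median SE rose from 0.0908 to 0.116 or 0.119, so calls ended mostly because the error rose. For Dp(16)1/Df(16)8 against +/+ (92 and 37), DESeq2 gave 145 and 85, limma voom 158 and 98, females 45 and 4, males 53 and 10, the blocks 166 and 107, and a fold of 1.2 48 and 4; outside the segments only, the 2 genotypes alone gave 22, leaving out high Ttr 12 and low Gm28437 18. Between the aneuploid genotypes (8 and 6), each sex alone gave 5 genes in all, the blocks 2 and 2, and the Gm28437 level, alone or with the striatal score, 0 and 0, because it separates these genotypes and raised the median SE of the 6 genes from 0.291 to 0.848. DESeq2 called 2 genes whose change differed by sex in Dp(16)1/Df(16)8. Sex here is the label, so the females include Dp(16)1/Df(16)8 replicate 2, which had Y-linked transcripts.

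Of the gene lists passing (13, 10 and 2), an estimated correlation left 1, 1 and 0. By fry 5, 1 and 0 lists passed. In Ts65Dn;Df(17)2 these were the distal chromosome 16 segment, excitatory neurons (adjusted p by fry 0.0438), interferon-stimulated genes (0.0438), interneurons (0.00666) and matrix genes (0.0147). The matrix list had not passed camera. Between the aneuploid genotypes, 2 surrogate variables, the animals from 30000 and the striatal score each gave 5, and the Gm28437 level 7. The striatal list reversed with 2 surrogate variables (adjusted p 0.665 and 0.487 against +/+) and, by construction, with its own score (0.773, and 0.657 between the aneuploid genotypes), and the unfolded protein list in Ts65Dn;Df(17)2 with the Gm28437 level (0.966). The chromosome 17 fold of Ts65Dn;Df(17)2 passed with the mean over genes (1.084) and without animals below 30000 (1.035). The correlation of the shared change was 0.58 with the striatal score. The 250 named gene results include many genes that were not called, and these count as the same when they stayed so. The same were 227 with DESeq2, 246 with its size factors, 207 with 2 surrogate variables and 218 without animals below 30000. With the striatal score 205 were the same, and with the Gm28437 level 193. DESeq2 added 23 calls. Lost calls were 40 with 2 surrogate variables (3 added), 29 without animals below 30000 (3 added), 41 with the striatal score (4 added) and 57 with the Gm28437 level. Of the called results 0 reversed.

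Leaving out each library gave 264 to 1486 genes (201 to 1416 outside) in Ts65Dn;Df(17)2, 74 to 222 (21 to 164) in Dp(16)1/Df(16)8 and 7 to 10 (5 to 8) between them. The count that differed by sex was 0 in Ts65Dn;Df(17)2 and 0 to 2 in the others. Segment folds of Ts65Dn;Df(17)2 ran from 1.492 to 1.507 (distal chromosome 16), 0.9881 to 1.02 (Lipi to Ncam2) and 1.019 to 1.035 (chromosome 17), and those of Dp(16)1/Df(16)8 from 1.511 to 1.52, 0.9915 to 1.037 and 1.012 to 1.029. Without Dp(16)1/Df(16)8 replicate 1, which stands apart in them, the meningeal list (adjusted p 0.0294, and 0.618 with an estimated correlation) and Col25a1 (log2 0.52) passed against +/+ in that genotype. The interaction test recovered 20.9% of simulated 1.5-fold differences in Ts65Dn;Df(17)2.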

Other observations

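A pair of predicted transcripts on chromosome 16, just before the segment from Lipi to Ncam2, was lower in Dp(16)1/Df(16)8 than in +/+. Gm49674 (74873039 to 74875938) fell by 0.41 on the log2 scale (SE 0.088, adjusted p = 0.0113 by edgeR), from 38.3 ± 5.64 to 28.8 ± 3.51 CPM (SD, n = 12 and n = 10). A630036G19Rik (75030852 to 75034931) fell by 0.41 (SE 0.093, adjusted p = 0.0232 by edgeR), from 67.6 ± 11.8 to 51 ± 6.91 CPM. Neither passed in Ts65Dn;Df(17)2, with log2 fold changes of -0.09 and -0.06, and the aneuploid genotypes did not differ by edgeR in either, with an adjusted p of 0.762 for both. Both genes were chosen after their values were seen, and no explanation was tested.

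In the following, the tests of additional copies, of coat colour markers, of animal numbers and of the shift that mitochondrial genes could show were chosen only after the result was seen. Tyr and transcripts next to the segments' ends were high in Ts65Dn;Df(17)2. An additional copy alone is argued against for C87487, Gm49806 and Tyr, whose ratios to +/+ had lower bounds of at least 26.4, and for A730009L09Rik, whose fitted fold had a lower bound of 4.58, but B230307C23Rik, at 1.54 (95% interval 1.36 to 1.74), had the value of 1 additional copy. Striatal tissue is argued against because +/+ libraries with matching scores had at most 2.14% of the Ts65Dn;Df(17)2 level of C87487, Gm49806 and Tyr. For Tyr, a candidate explanation is a coat colour marker carried by a chromosome engineering vector: nonagouti, another such marker, had counts in 10 of 10 Dp(16)1/Df(16)8 libraries (2 to 16) and 9 of 10 Ts65Dn;Df(17)2 libraries (0 to 9), at least 35.3-fold and 16.1-fold higher than a floor of 3 counts over the +/+ group, which had 0 in 12 libraries. The labels name no such marker, counts per gene cannot locate the source, and a strain difference at nonagouti and an effect of the new neighbourhood on transcripts at the junction stay open and untested.

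Gm28437 split the +/+ libraries into 5 with 4 to 10 counts and 7 with 26 to 37, while Ts65Dn;Df(17)2 had 3 to 8 and Dp(16)1/Df(16)8 25 to 50. The split followed the animal numbers: leaving other +/+ animals aside, in 11 of 12 +/+ libraries the nearest aneuploid animal by number was of the genotype with the same level. Between these 2 sets of +/+ libraries, which were defined by Gm28437, it was the 1 gene of 15679 that differed by edgeR (adjusted p = 0.0327), with 561 genes at an unadjusted p under 0.05. Of 11 other tested genes within 50 kb or on the mitochondrial chromosome 0 differed by edgeR, and 0 at an unadjusted p under 0.05. A different mitochondrial genome stays open all the same, because in 9 of the 10 mitochondrial genes the difference of 2.86 CPM in Gm28437 would be less than 2 SE.

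On the rest of chromosomes 16 and 17, 48 of 1081 tested genes (4.44%) changed in Ts65Dn;Df(17)2, against 524 of 14828 (3.53%) on other chromosomes, and Fisher's exact test, two-sided, gave p = 0.127.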
